A study of Mus musculus with 2 samples.

How the data were processed

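H3K4me3 was measured by chromatin immunoprecipitation and sequencing in 2 biological replicates of mouse heart at embryonic day 15.5, pools of hearts from 78 and 62 embryos. The labels name a control experiment. The deposited material used here is 4 peak lists in narrowPeak format on the mouse genome mm10, per the text files deposited with the samples: a list for each replicate, a pooled list called on both replicates together, and a replicated list derived from the pooled list and the replicate lists. Peaks were therefore called by the authors both per replicate and on pooled data. The aligner, the peak caller, their versions and the read filters are not given in the sources used here.

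Each peak in the deposited lists has a signal value that is never negative, with no scale stated, and the −log10 of a p-value and of a q-value, which the authors computed against the control. The lowest −log10 p-value in the deposited lists was 2.00, so a p-value threshold of 0.01 fits them. The files hold no counts and no library totals, so the depth per replicate is unknown and no interval for depth is given. Differences in depth or enrichment between the replicates can change how many weak peaks are listed and where a peak ends. The 2 replicate lists shared no peak with identical coordinates. All peaks on the main chromosomes lay within the chromosome lengths of the reference genome. The 10 to 12 peaks of each list on other sequences were not checked.

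Gene annotation was GENCODE mouse release 21 on the same genome build. A promoter was the window of 1000 bp either side of a transcript start. For the marks and breadths of genes, protein-coding genes had the starts of their protein-coding transcripts and other genes those of all their transcripts. For the shares of peaks, bases and genome at promoters, the windows were those of all 132666 annotated transcript starts. A gene was marked where a peak overlapped a promoter window by at least 1 bp. Domains were peaks of a list merged across gaps of up to 1000 bp, and the breadth of a gene was the length of the widest domain with a peak over its promoter window. Coordinates are 1-based. Each peak was assigned to promoter, exon, intron or intergenic sequence in that order. An overlap of at least 1 bp with a window made it a promoter peak, and the position of its listed summit decided among the other classes. The bases of the broadest domains were assigned to exon, intron or intergenic sequence, with no promoter class. Several genes can share a domain, and a marked promoter can belong to a neighbouring gene.

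Before the data were examined, 24 gene lists were fixed: cardiac transcription factors; sarcomere of cardiomyocytes; cardiac calcium handling, ion channels and natriuretic peptides; signalling in heart development; transcription factors of other lineages; Hox genes; pluripotency and germline; housekeeping; oxidative phosphorylation; fatty acid oxidation and its regulators; cell cycle; imprinted genes; sex-linked genes. The lists of cell types were endothelium and endocardium, epicardium and fibroblasts, smooth muscle and pericytes, erythroid cells, macrophages, lymphocytes, neurons with neural crest and Schwann cells, hepatocytes, skeletal muscle, and lung and other epithelium, and the last list was all olfactory receptor genes. After the data had been seen, lists of T-lineage cells of the thymus (24 genes) and thymic epithelium (15 genes) were added, before the values of their members were looked at.

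The share of marked genes in each list was compared with the other genes of the same annotation classes by a two-sided Fisher's exact test. The median breadth of the marked protein-coding members was compared with 10000 random lists of the same number of marked protein-coding genes, for lists with at least 5 marked members, in a two-sided permutation test. The p-values were adjusted by the Benjamini-Hochberg method over the 24 lists and over the 20 lists tested for breadth, with a threshold of 0.05. These tests compare sets of genes within 1 tissue, and genes are not replicates of animals. Neighbouring genes of a list, such as Hoxa1 and Hoxa2 under a shared domain, were counted as separate units, although they are not independent. Values of the replicates are given as mean ± SD with n = 2, which leaves no room for a test between them.

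The genes named were fixed before the data were examined: in each list, the 2 marked members with the broadest domain and the member without a replicated peak that comes earliest in the alphabet; the genes at the 15 broadest domains and at the 10 peaks of highest signal; and Gata4, Nkx2-5, Tbx5, Myh6, Myh7, Tnnt2, Nppa, Myl2, Myl7, Alb, Xist, Ddx3y and Gapdh. Names outside this rule, such as Upk3b, the marked macrophage, germline, olfactory receptor and Y-linked genes, Pou5f1, Nanog, Myog, the globin genes and the thymus, lymphoid, epithelial and metabolic genes of the closing section, were chosen after their values were seen.

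The tests were tried on simulated data. For the lists marked at promoters, Fisher's exact test recovered 97.5% of lists of 20 genes marked at a share of 98% and called 0% of unchanged lists, over 21815 genes. For the breadth of gene lists, the permutation test recovered 20% of lists of 20 genes made 25% broader, 85% of those made 1.5 times broader and 100% of those made 2 times broader, and called 0% of unchanged lists, over 14766 genes. Small differences in breadth can therefore have been missed. The simulated marks and breadths were placed on genes at random, with no tie to the CpG content of the promoter. The 0% therefore does not carry over to real lists whose CpG content differs from that of other genes. The alternatives were other promoter windows (500 and 2500 bp), 1 start per gene, other gaps (0 and 3000 bp), an overlap of 50% of the peak, peaks with a −log10 q-value of at least 5, the 50% of peaks with the highest signal, lists of equal length, the pooled list, the list of each replicate in place of the replicated list, covered bases within 5000 bp, and random lists matched on the CpG ratio (observed over expected) of the 1000 bp around the start. Python 3.11.15 was used with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9 and pysam 0.24.0, with samtools 1.23.1 for the genome index.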

Results

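Trimethylation of histone H3 at lysine 4 (H3K4me3), a histone mark found mainly at active and poised gene promoters, was mapped by chromatin immunoprecipitation and sequencing in hearts of mouse embryos of strain B6NCrl at embryonic day 15.5. The series has 1 group of 2 biological replicates. Replicate 1 was a pool of hearts from 78 embryos and replicate 2 a pool from 62 embryos, both of mixed sex, so the replicates were separate pools of animals. With 1 group there was no treatment, stage or tissue to compare with. The comparisons were between the replicates, between the peak lists, and between sets of genes within the heart. The authors' lists held 31857 peaks for replicate 1 and 33562 for replicate 2. Their list called on both replicates together, the pooled list, held 34791, and their list of replicated peaks held 27364. The lists give no read counts, so the sequencing depth behind each peak is unknown. Wilson 95% intervals below cover counting error over peaks or genes only. The signal of a peak is the authors' own value, whose scale is not stated, and it was used to describe, rank and filter peaks.

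The strongly marked regions of the 2 heart pools were largely shared, and the peaks found in a single replicate were short and weak. Of the replicate 1 peaks, 87.8% (95% interval 87.5 to 88.2, n = 31857 peaks) overlapped a replicate 2 peak by at least 1 bp. Of the replicate 2 peaks, 82.6% (82.15 to 82.96, n = 33562) overlapped a replicate 1 peak. The 3879 peaks of replicate 1 alone had a median width of 253 bp and a median signal of 2.92, against 1136.5 bp and 15.4 for its shared peaks. The 5853 peaks of replicate 2 alone had medians of 258 bp and 3.02, against 1197 bp and 16.9. Promoter windows, within 1000 bp of an annotated transcript start, took in 21.8% of the peaks of replicate 1 alone and 29.2% of those of replicate 2 alone, against 65.0% and 65.1% of the shared peaks.

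Where both pools had a peak, the order of the regions by signal was much alike. Merging peaks of both lists across gaps of up to 1000 bp gave 28108 domains, and 23368 of them held a peak of each replicate. Across these domains, which are not independent replicates, Spearman's rho of the highest signal was 0.928 (95% interval 0.926 to 0.930), and Pearson's r of log2 signal was 0.96. The interval treats domains as independent and does not cover variation between pools. Breadth was ordered alike too: across 14668 protein-coding genes marked in both pools, rho of domain breadth was 0.924, and the median ratio of breadth in replicate 2 over replicate 1 was 1.03.

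The peaks that the authors kept as replicated were the broad and strong ones. Of the pooled peaks, 78.7% (95% interval 78.2 to 79.1, n = 34791) were in the replicated list, each with unchanged coordinates. Kept peaks had a median width of 1317 bp and a median signal of 18.6, and 64.7% of them lay at a promoter. The 7427 peaks left out had a median width of 255 bp and a median signal of 2.54, and 24.9% lay at a promoter. Among the replicated peaks, 1474 did not overlap a peak of each replicate even by 1 bp, and their median signal was 3.09; the rule that kept them is not given in the sources used here.

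H3K4me3 in the embryonic heart lay mainly at gene starts. Of the replicated peaks, 17692, or 64.7% (95% interval 64.1 to 65.2, n = 27364), overlapped a promoter window, and these peaks were wide (median 1912 bp) and strong (median signal 40.2). Promoter windows made up 5.88% of the genome and held 67.0% of the bases under replicated peaks. Away from promoters, 4323 peaks were intergenic, 4246 lay in introns and 1103 in other exons, with median signals of 5.92, 4.23 and 5.69. The share at promoters was 59.8% in replicate 1 and 58.8% in replicate 2 (mean 59.3% ± 0.698, SD, n = 2), below that of the replicated list by more than the spread between replicates. Among the 50% of replicated peaks with the highest signal it was 93.1%.

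The 10 peaks of highest signal stood at promoters, and none of these promoters belonged to a gene of the fixed lists. The highest, with a signal of 82.2, covered the start of Dyrk1b, a protein kinase gene, over 2008 bp of chromosome 7 (28179162 to 28181169). It was followed by the peaks at Srp19, which codes for a subunit of the signal recognition particle (81.4), and Rpsa, which codes for a ribosomal protein (81.0). Next were the peak shared by Ccdc47 and Ddx42 (80.8), the peak at Nup133, a nuclear pore gene (80.8), and the peak at Tomm40, a gene of the mitochondrial import pore (80.5). The peak shared by Adprm and Sco1 had a signal of 80.3, that at Usp22 79.99, that at Sbno1 79.8, and that shared by Catsper2 and Pdia3 79.5. Their widths ran from 1731 bp at Tomm40 to 3521 bp at Catsper2 and Pdia3.

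The broadest domains lay over other genes, and 7 of the 15 broadest covered a gene of the cardiac transcription factor list. These lengths, their order and this count hold for peaks merged across gaps of up to 1000 bp. The broadest, 21310 bp on chromosome 14 (63231679 to 63252988), lay inside Gata4 (ENSMUSG00000021944.15), which codes for a transcription factor needed to form the heart, with 94.2% of its length in introns and 5.78% in exons. It measured 20908 bp ± 709 (SD, n = 2) in the replicates. The domain was merged from 7 peaks that covered 20182 bp, the widest of them from 63242214 to 63250978. The widest single replicated peak of all, at 13774 bp, lay elsewhere. The domain over Nkx2-5 (ENSMUSG00000015579.5), the homeobox gene of the early cardiac lineage, reached 18199 bp on chromosome 17 (26835771 to 26853969; 17940 bp ± 158, SD, n = 2), and 65.1% of it was intergenic. Hand2, a regulator of right ventricle formation, had 18151 bp (15873.5 bp ± 2642). Myh7, the beta myosin heavy chain of the fetal ventricle, had 16157 bp on chromosome 14 (54981714 to 54997870; 17059 bp ± 1338). The other domains over cardiac factors of the list were those of Tbx2 (16042 bp), Gata6 (15539 bp), Tbx20 (15508 bp) and Meis1 (14501 bp). Outside the heart lists were the domains over the transcription factor genes Meis2 (16897 bp), Nfib (16729 bp) and Irx5 (13823 bp), and those over Hoxa1 and Hoxa2 together (14267 bp), Rhof and Setd1b together (13948 bp), the histone demethylase gene Kdm6b (13803 bp) and Bahcc1 (13679 bp). The 2 replicates differed most at Tbx2, with 9983 bp in replicate 1 and 15991 bp in replicate 2.

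**Figure D1:**
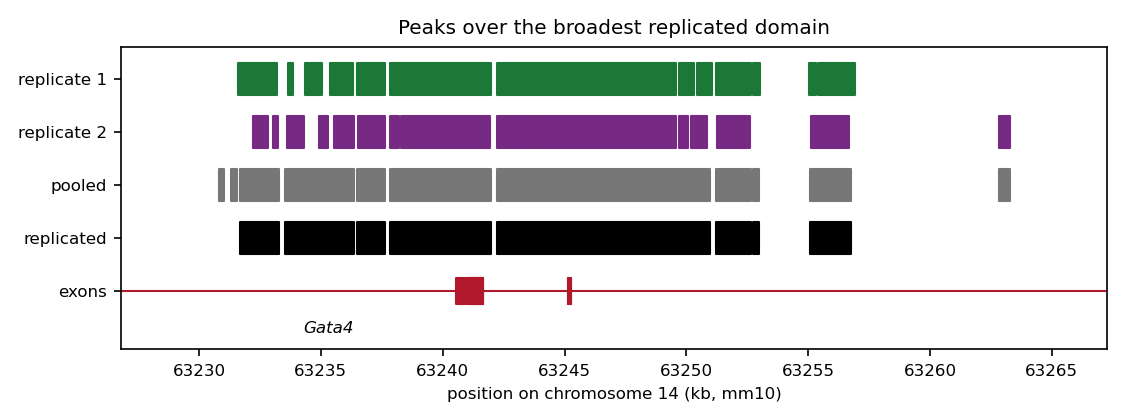
Peaks over the broadest replicated domain, at Gata4, in the replicate 1, replicate 2, pooled and replicated lists (bars, to scale), with annotated exons in red, against position on chromosome 14 in kb of mm10. The replicated peaks from 63231679 to 63252988 form the 21310 bp domain, and a separate peak lies to its right in all 4 lists.

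Of 21866 protein-coding genes, 14766 carried a replicated peak at a promoter, 67.5% (95% interval 66.9 to 68.1). The share was 67.4% in replicate 1 and 68.2% in replicate 2 (mean 67.8% ± 0.582, SD, n = 2). Both pools marked 14668 genes, while 64 were marked in replicate 1 alone and 244 in replicate 2 alone. In the pooled list, the genes marked in a single pool had median signals of 2.99 and 2.97, against 47.9 for genes marked in both. Genes on the X chromosome were marked in 52.8% of cases (501 of 948), and on the Y chromosome 4 of 183 were marked. Other classes of gene had lower shares: 38.0% of antisense genes, 17.1% of lincRNA genes and 2.41% of processed pseudogenes.

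Genes of the cell types that make up the heart were nearly all marked. All 20 cardiac transcription factor genes, 20 sarcomere genes, 20 genes of calcium handling, ion channels and natriuretic peptides, 20 genes of signalling in heart development and 20 genes of endothelium and endocardium carried a replicated peak, as they did in each replicate (each list: 95% interval 83.9 to 100; Fisher's exact test against the other protein-coding genes, two-sided, adjusted p = 0.00101). With the 50% of replicated peaks of highest signal, the endothelial list (10 genes, adjusted p = 0.569) and the calcium handling list (16 genes, adjusted p = 0.0903) lost their calls in Fisher's exact test. Of the 20 epicardial and fibroblast genes, 18 were marked (adjusted p = 0.0420, Fisher's exact test), among them Wt1 and Pdgfra, while Msln and Upk3b had no peak in either replicate. That call was lost with replicate 1 alone (17 genes, adjusted p = 0.115), with replicate 2 alone (18 genes, adjusted p = 0.0612) and under 4 further alternatives, with adjusted p from 0.0388 to 0.682 over all 8 (Fisher's exact test). Of the 14 smooth muscle and pericyte genes, 13 were marked, and Mylk, the myosin light chain kinase gene, had a peak in replicate 2 alone (945 bp; adjusted p = 0.0583, Fisher's exact test). The list was called more often marked with replicate 2 alone (14 genes, adjusted p = 0.0105) and with 1 start per gene (adjusted p = 0.0331), and adjusted p reached 0.645 over the 8 alternatives (Fisher's exact test).

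The lists of housekeeping (25 of 25, adjusted p = 0.000454), cell cycle (18 of 18, adjusted p = 0.00255), oxidative phosphorylation (15 of 15, adjusted p = 0.00626) and fatty acid oxidation genes (14 of 14, adjusted p = 0.0104) were each marked more often than other genes by Fisher's exact test. Of 20 imprinted genes, 19 were marked (adjusted p = 0.000507, Fisher's exact test), with Ndn the exception. This list has non-coding members, so it was compared with genes of non-coding classes too, and 55.0% of the genes compared were marked. Regulators of other lineages were marked too. All 24 transcription factor genes of the list for other lineages, such as the forebrain gene Emx1 (domain of 5295 bp) and the midbrain and hindbrain gene Gbx2 (5011 bp), carried a peak in both replicates, and so did 35 of 39 Hox genes, with 37 of 39 in the replicated list (both lists: adjusted p = 0.000454, Fisher's exact test). The median signal was 15.4 for the other-lineage factors and 9.70 for the Hox genes, against 18.6 for endothelial, 26.5 for epicardial and fibroblast and 45.2 for cardiac factor genes. With the 50% of replicated peaks of highest signal, 37.5% of the other-lineage factors (adjusted p = 0.0554) and 23.1% of the Hox genes (adjusted p = 7.89e-05, both Fisher's exact test) were marked, shares below those of other genes. With all replicated peaks, shares were also set against random lists matched on the CpG ratio of the promoter, after the data were seen. Housekeeping and cell cycle genes (matched medians 100%), other-lineage factors (95.8%) and Hox genes (92.3%) lay within the central 95% of these lists. Oxidative phosphorylation and fatty acid oxidation genes lay above their upper limits, 93.3% and 92.9%.

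Hepatocyte, macrophage, erythroid, germline and olfactory receptor genes were marked less often than other protein-coding genes. Macrophage (18.8%) and erythroid genes (33.3%) were not rarer than random lists matched on the CpG ratio of the promoter, whose median marked shares were 18.8% and 27.8%, a comparison chosen after the data were seen. In that comparison hepatocyte genes (11.1%, matched median 27.8%) lay at the lower limit of the central 95% of matched lists, 11.1%, and not below it, while pluripotency and germline genes (25%, matched median 81.3%) lay below theirs, 68.8%. Of 18 hepatocyte genes, 2 were marked (11.1%, 95% interval 3.10 to 32.8; adjusted p = 1.34e-05, Fisher's exact test): Apoh, whose 3377 bp domain also covered the promoter of Prkca, and Apoa1 (1152 bp), which had no peak in replicate 1 and left that pool with 1 marked gene. Alb and Afp, the albumin and alpha-fetoprotein genes, had no peak in either pool. Of 16 macrophage genes, Cd14 (1655 bp), Ptprc (1119 bp) and Spi1 (544 bp) were marked (adjusted p = 0.000454, Fisher's exact test), and replicate 2 alone marked 6 (adjusted p = 0.0178, Fisher's exact test). Of 18 erythroid genes, 6 were marked (adjusted p = 0.00624, Fisher's exact test), Tal1 with 5162 bp and Epor, the erythropoietin receptor gene, with 2721 bp, but none of the 7 globin genes, nor Alas2 of red cell haem synthesis, had a peak in either replicate. Of 16 pluripotency and germline genes, Dazl, Dppa3, Esrrb and Fgf4 were marked (adjusted p = 0.00111, Fisher's exact test) and Pou5f1 and Nanog were not. Of 1134 olfactory receptor genes, 5 were marked, namely Olfr56, Olfr94, Olfr607, Olfr658 and Olfr1033 (0.441%, 95% interval 0.188 to 1.03). Some globin and olfactory receptor genes have near-identical copies, where reads can fail to map to 1 place, and how such reads were treated is not given in the sources used here. The marked share of olfactory receptor genes was not set against lists matched on the CpG ratio, so a part of that ratio in it stays open.

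The remaining lists did not pass the threshold. Neuronal and neural crest genes (14 of 18) and lung and other epithelial genes (14 of 18) each had an adjusted p of 0.455 by Fisher's exact test. Skeletal muscle genes (9 of 20, adjusted p = 0.0627, Fisher's exact test) included Mylpf (3762 bp, a domain that also covered the promoter of Tbc1d10b) and the muscle creatine kinase gene Ckm (3669 bp), but not Cacna1s or Myog. Skeletal muscle was called less often marked with replicate 1 alone (8 genes, adjusted p = 0.0186), with replicate 2 alone (9 genes, adjusted p = 0.0398) and under 3 further alternatives, with adjusted p from 0.000373 to 0.112 over all 8 (Fisher's exact test). Lymphocyte genes (7 of 16, adjusted p = 0.0670, Fisher's exact test) differed between the pools, with 4 marked in replicate 1 and 8 in replicate 2, and replicate 1 alone gave a call of less often marked (adjusted p = 0.00117), as did 3 further alternatives, with adjusted p from 0.000511 to 0.201 over all 8 (Fisher's exact test). Of 6 sex-linked genes, Xist (3623 bp), Ddx3y (1636 bp), Eif2s3y, Uty and Kdm5d were marked in both pools of mixed sex, and Sry was not (adjusted p = 0.267, Fisher's exact test). In all, 13 of the 24 lists were marked more often than other genes, 5 less often and 6 did not pass.

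**Figure D2:**
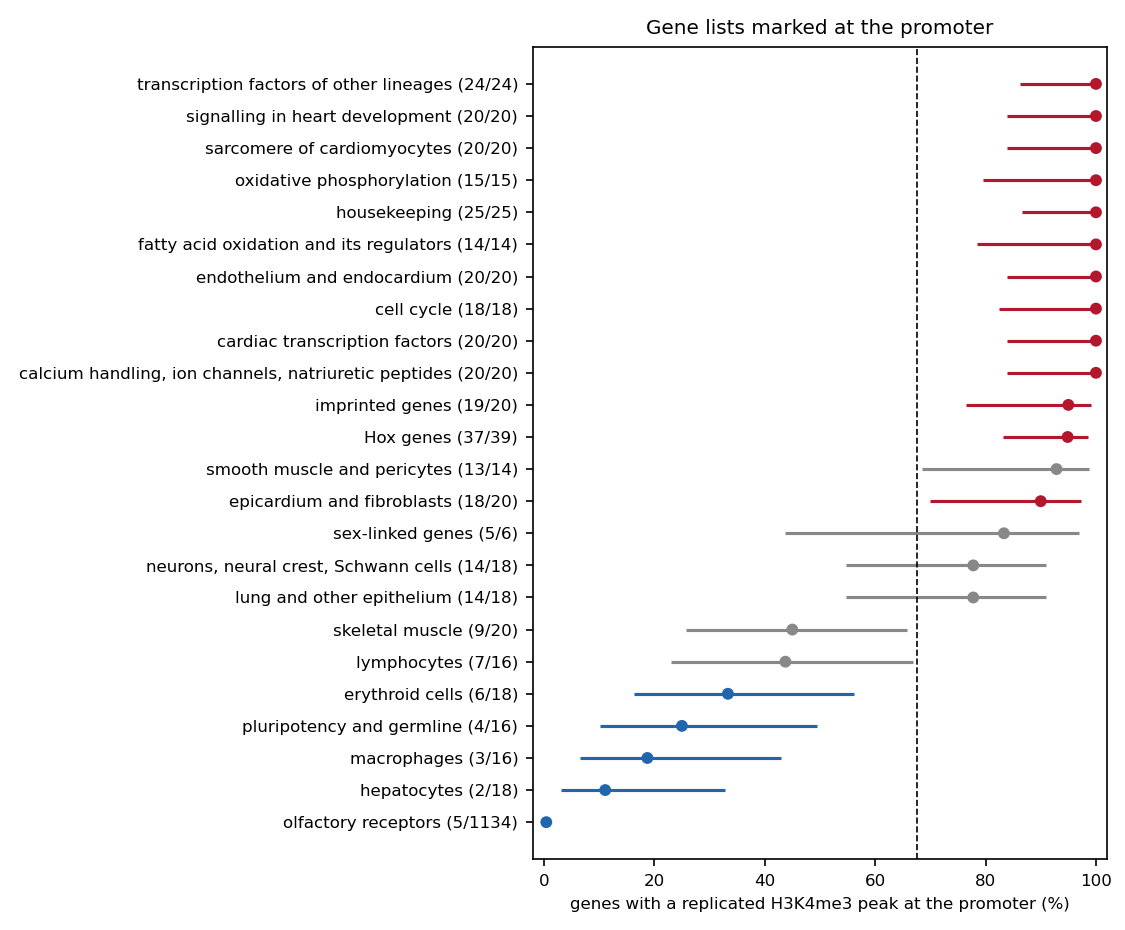
Share of each gene list with a replicated H3K4me3 peak at the promoter, in percent (points), with Wilson 95% intervals (lines) and the marked and annotated gene numbers in parentheses. Red lists were marked more often and blue lists less often than other genes, grey lists did not pass the test, and the dashed line is the 67.5% of all protein-coding genes. The imprinted and sex-linked lists were compared with genes of non-coding classes too, so the line is not their comparison.

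Domains over 6 of the 7 lists of heart genes had medians 2.0 to 3.1 times those of random lists of marked genes, and smooth muscle and pericyte genes did not pass the test (2825 bp, 1.22 times, adjusted p = 0.253, permutation test). The median breadth over all marked protein-coding genes was 2319.5 bp (quartiles 1716 and 3141 bp). The 20 cardiac transcription factor genes had a median of 7233 bp in the replicated list (mean of the replicates' medians 7011 bp ± 87.3, SD, n = 2), 3.13 times the 2309 bp of random lists of equal size. Tbx5, needed to form the atria and conduction system, had 12837 bp (12493.5 bp ± 1944, SD, n = 2). The 20 sarcomere genes had a median of 7020 bp (6938 bp ± 2.83), with Actc1, the cardiac actin gene, at 11272 bp, Myh6, the alpha myosin heavy chain gene, at 11130 bp, Tnnt2, the cardiac troponin T gene, at 8541 bp and Myl2, the ventricular light chain gene, at 7831 bp. Both medians were above those of every random list (permutation test with 10000 random lists, two-sided, adjusted p = 0.00067; 0.00020 is the smallest raw p they can give).

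The medians of 4 further heart lists lay between 4522.5 and 4734.5 bp. Endothelial and endocardial genes had 4734.5 bp, led by Nfatc1, a regulator of heart valve formation (9463 bp), and Fli1 (8386 bp). Genes of signalling in heart development had 4723.5 bp, led by the Notch ligand gene Dll4 (13539 bp; 7680 bp in replicate 1 and 13251 bp in replicate 2) and Smad6 (8892 bp). Epicardial and fibroblast genes had 4684 bp, led by Pdgfra (9059 bp) and the epicardial gene Wt1 (8485 bp). Genes of calcium handling, ion channels and natriuretic peptides had 4522.5 bp, led by Gja1, the connexin 43 gene (10111 bp), and the sodium-calcium exchanger gene Slc8a1 (9767 bp). Each of these 4 lists also had an adjusted p of 0.00067 in the permutation test. Broad domains did not cover every heart gene. Nppa, the atrial natriuretic peptide gene, had a domain of 2000 bp with a signal of 4.85 (1517.5 bp ± 428, SD, n = 2), and Myl7, the atrial light chain gene, had 2719 bp.

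By the same permutation test, broader domains were also found over housekeeping genes (3743 bp, adjusted p = 0.00114), with Gapdh at 6587 bp and Chmp2a at 6106 bp in a domain shared with Ube2m, and over imprinted genes (3729 bp, adjusted p = 0.0040), with the growth factor gene Igf2 at 12141 bp and Grb10 at 7646 bp. Cell cycle genes (3174.5 bp, adjusted p = 0.0218), led by the cyclin genes Ccnd2 (8051 bp) and Ccnd1 (6477 bp), fatty acid oxidation genes (3223.5 bp, adjusted p = 0.0271), led by the coactivator genes Ppargc1b (6377 bp) and Ppargc1a (4558 bp), and the other-lineage factors (2986.5 bp, adjusted p = 0.0315) passed the same permutation test by smaller margins. In the permutation test with replicate 2 alone, the fatty acid oxidation list (2966 bp, adjusted p = 0.0997) and the other-lineage factors (2869 bp, adjusted p = 0.0699) no longer passed. With no merging of peaks the other-lineage factors had 1884 bp, below random lists (adjusted p = 0.156, permutation test), and over 9 alternatives adjusted p ran from 0.00461 to 0.205 for them and from 0.00080 to 0.0997 for the fatty acid oxidation list.

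Narrower domains were found over Hox genes (1815 bp, 37 marked, adjusted p = 0.0140), lymphocyte genes (1142 bp, 7 marked, adjusted p = 0.0058), skeletal muscle genes (957 bp, 9 marked, adjusted p = 0.0015) and olfactory receptor genes (680 bp, 5 marked, adjusted p = 0.0018) in the permutation test. Lymphocyte genes lost the call with replicate 2 alone, where their median was 2079.5 bp over 8 genes (adjusted p = 0.711, permutation test), and against random lists matched on the CpG ratio of the promoter (adjusted p = 0.464, permutation test). They also lost it as bases covered within 5000 bp (2214 bp, adjusted p = 0.695), with adjusted p from 0.00461 to 0.711 over 7 alternatives (permutation test). Olfactory receptor genes also lost it against matched lists (adjusted p = 0.0808, permutation test), and their median was 1028 bp with replicate 2 alone. Skeletal muscle genes had 1666 bp with gaps of up to 3000 bp and with the pooled list, and no longer passed (adjusted p = 0.0642 and 0.0879), nor as bases covered (1666 bp, adjusted p = 0.0697), with adjusted p from 0.00050 to 0.0879 over 9 alternatives (permutation test). Hox genes lost it with replicate 2 alone as well (2030.5 bp, adjusted p = 0.277), and merging across gaps of up to 3000 bp gave them 4638 bp, above random lists (adjusted p = 0.00050, permutation test; up to 0.695 over 9 alternatives). Besides smooth muscle, the breadth of lung and other epithelial (2781 bp, adjusted p = 0.253), oxidative phosphorylation (2747 bp, adjusted p = 0.261), neuronal (2363 bp, adjusted p = 0.905) and erythroid genes (1959 bp, adjusted p = 0.407) did not pass the permutation test. Smooth muscle genes were called broader with replicate 2 alone (3125.5 bp, adjusted p = 0.0488) and under 3 further alternatives, with adjusted p from 0.0135 to 0.619 over all 9, and lung and other epithelial genes under 2, with adjusted p from 0.0229 to 0.452 (permutation test). Of the 20 lists with at least 5 marked members, 11 were broader, 4 narrower and 5 not past the threshold.

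**Figure D3:**
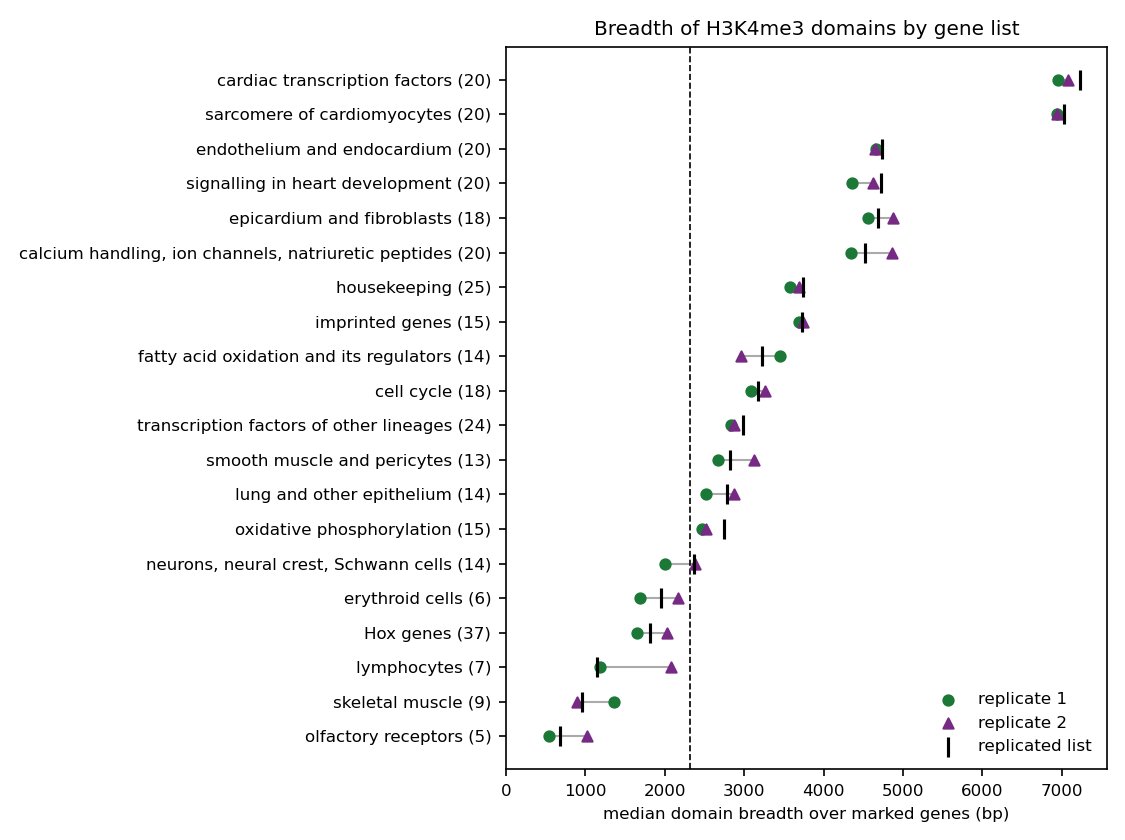
Median breadth of H3K4me3 domains over the marked genes of each list, in bp, in replicate 1 (circles), replicate 2 (triangles) and the replicated list (bars), with the number of genes marked in the replicated list in parentheses. The median of a replicate is over the genes marked in that replicate, for lymphocyte genes 4 in replicate 1 and 8 in replicate 2. The dashed line is the 2319.5 bp median of all marked protein-coding genes, cardiac transcription factors and sarcomere genes lie farthest right at 7233 and 7020 bp, and lymphocyte genes are farther right in replicate 2 than in replicate 1.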

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

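All alternatives were planned except the one named as chosen after seeing the data, and where a result moved the cause was not tested unless stated. The overlap of the replicates, 85.2% on average over both directions, was 92.6% with a −log10 q-value of at least 5 in both lists, 96.0% in the 50% of peaks with the highest signal and 90.2% for merged domains; a stricter q-value in the queried list alone, chosen after seeing the data, gave 97.3%. Leaving out a replicate leaves no overlap or correlation to compute. Rho of signal moved from 0.928 to 0.904 with the stricter q-value, 0.936 with no merging, 0.975 for −log10 p-values and 0.969 for covered length. Pooled peaks kept rose from 78.7% to 95.6% with the stricter q-value and 86.4% for domains. The share of replicated peaks at promoters (64.7%) was 61.8% and 71.7% with windows of 500 and 2500 bp, by their construction, 66.4% with the stricter q-value, 93.1% in the 50% with the highest signal, 56.2% in the pooled list, and 58.8% to 59.8% with a single replicate. Marked protein-coding genes (67.5%) were 68.5% with windows of 2500 bp, 64.9% with 1 start per gene, 58.7% with the 50% of highest signal, 68.4% in the pooled list, and 67.4% to 68.2% with a single replicate.

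Of the 18 list calls at promoters, 16 to 19 were made under each alternative, and 13 (the 50% of peaks with the highest signal) to 18 were the same lists in the same direction. Among those peaks, marked shares fell below those of other genes for other-lineage factors (37.5%), Hox genes (23.1%) and endothelium (50%), which passed the test for Hox genes alone. Of the 15 breadth calls, 11 to 16 were made, and 11 to 14 were the same lists in the same direction. Other-lineage factors turned to below random lists with no merging (1884 bp) and Hox genes to above them with gaps of 3000 bp (4638 bp). Breadths of single named genes were judged by another rule, so their counts cannot be compared with those of the list calls. With no merging, 42 moved by more than the SD between the replicates and 52 did not. With replicate 2 alone 46 moved and 48 did not, and with replicate 1 alone 49 moved and 45 did not. The SD comes from the same 2 replicate values, so the counts for a single replicate follow largely from the rule and say little of stability. The 6 heart lists called broader kept their breadth call under all 9 alternatives. No paired analysis was possible because there is 1 group. The unknown depth limits what can be said of weak peaks: a gene without a peak was not detected as marked, and is not shown to lack the mark.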

Other observations

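The tests in this part were chosen after the results had been seen, except those of CpG-rich promoters and of merging for the heart lists. The T-lineage test was prompted by the lymphocyte genes and chosen before the values of the T-lineage genes were seen. For a more complete replicate 2 list, the first test was the share of lymphocyte genes wider in replicate 2; it gave 100%, as did the upper limit of the central 95% of matched random lists, so it decided nothing, and the median difference in breadth replaced it after that was seen. The thymic epithelium list was written before its values were seen, but its test was added after. For cells of other organs, the first test, against all other protein-coding genes (52.7% against 67.6% marked, p = 0.00862, Fisher's exact test), did not allow for CpG content and was replaced by one against matched lists. A p-value for genes wider in replicate 2 compares sets of genes between 1 pair of pools, with genes as the units, and is no test between pools.

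Most fatty acid oxidation genes had broader domains in replicate 1. Of these 14 fatty acid oxidation genes, 2 (Acadvl and Cd36) were broader in replicate 2, or 14.3%, against 61.8% of other protein-coding genes (Fisher's exact test, adjusted p = 0.00954 over 26 lists), and the median difference, replicate 2 minus replicate 1, was -274.5 bp. Cpt1b, the muscle form of the mitochondrial fatty acid importer, had 3460 bp in replicate 1 and 2935 bp in replicate 2, and Esrra, a nuclear receptor gene of mitochondrial metabolism, had 3447 and 2997 bp. These are values of 1 pool each. Oxidative phosphorylation genes did not pass (5 of 15 broader in replicate 2, adjusted p = 0.164, Fisher's exact test), and of the sarcomere genes 11 of 20 were broader in replicate 2 (adjusted p = 0.988, Fisher's exact test).

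The marked share of protein-coding genes differed with the CpG ratio of the promoter, from 9.41% of 6203 genes below 0.3 to 99.6% of 2371 genes at 0.9 or more. All 20 sarcomere genes were marked, against a median of 45% in random lists matched on CpG ratio and 60% at the upper limit of their central 95%. The endothelial list (100% against a matched median of 70%) and the epicardial and fibroblast list (90% against 60%) also lay above those upper limits, which were 85% and 75%, as did the calcium handling list (100% against 70%, upper limit 85%). Cardiac transcription factors (matched median 90%) and signalling genes (95%) did not, since their upper limit was 100%. Smooth muscle (92.9%, upper limit 78.6%), oxidative phosphorylation (100%, upper limit 93.3%) and fatty acid oxidation genes (100%, upper limit 92.9%) lay above theirs, while Hox genes (94.9% against a median of 92.3%), housekeeping (100% against 100%), cell cycle (100% against 100%) and the 16 protein-coding imprinted genes (93.8% against 93.8%) did not.

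All 8 lymphocyte genes with a promoter peak were wider in replicate 2 (adjusted p = 0.164, Fisher's exact test), such as Cd3d of the T cell receptor complex (205 bp in replicate 1 and 4599 bp in replicate 2) and the recombinase gene Rag1 (no peak and 1555 bp). Cd3d had 998 bp in the pooled list and 363 bp in the replicated list. In replicate 2 the signals were weak, 5.57 at Cd3d and 4.04 at Rag1. The median there was 3.02 for peaks of that pool alone and 16.9 for shared peaks. Whether a more complete replicate 2 list at weak promoters is the source stays open. The median difference of the lymphocyte genes, 1575.5 bp, lay beyond 384 bp, the upper limit of the central 95% of random lists matched on pooled signal. This cannot decide the question, because the list was picked for its greater width in replicate 2 and the same genes were tested. Thymus tissue in replicate 2 is a candidate source and only a hypothesis: the test of T-lineage genes did not pass (14 of 17 wider, 82.4% against 61.8%, p = 0.131, Fisher's exact test) and Cd4, Cd8a and Dntt had no peak, though the T-lineage median difference of 885 bp lay beyond the matched limit of 266 bp, and all 13 thymic epithelium genes with a peak were wider (100%, adjusted p = 0.0356, Fisher's exact test), with Foxn1, the regulator of that epithelium, at no peak and 3083 bp. The replicate 2 signal at Foxn1 was 3.73, and the gene had no replicated peak. Of the T-lineage and thymic epithelium genes with a peak, 10 of the 17 and 10 of the 13 also had a peak in replicate 1. Krt5 and Krt14 had none in either replicate, and several of the genes, such as Six1 and Pax9, act in other tissues. Epithelium of another organ stays open, since lung and other epithelial genes (13 of 14 wider, adjusted p = 0.164, Fisher's exact test) had a median difference of 664 bp against a limit of 237.5 bp, Hox (398.5 against 189 bp) and housekeeping genes (206 against 194 bp) also passed theirs, so a passed limit is not specific to a tissue, and more blood cells of every kind cannot be told apart, since 4 of 6 erythroid and 6 of 6 macrophage genes (together 83.3%, p = 0.148, Fisher's exact test) are too few to decide, although their median differences of 168 and 293 bp lay within their limits of 379.5 and 493.6 bp.

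The broad domains over the 6 heart lists called broader were weighed against the CpG content of promoters and against the merging of peaks. Against random lists matched on CpG ratio, 6 of the 6 lists stayed broader past the threshold, and with no merging 6 of 6 did too. Neither the CpG ratio near the start nor the merging of peaks therefore accounts for the pattern alone. The ratio was taken over 1000 bp and does not measure how far a CpG-rich stretch extends, so that length stays open. CpG ratio and merging were not tested together. The number of cells that carry the mark is not in the peak lists, so whether it goes with breadth stays open. The level of the mark is held only as a signal value of unstated scale. Median signal and breadth of the lists were not in the same order. Housekeeping genes had 56.2 and 3743 bp, and cardiac factors 45.2 and 7233 bp. Sarcomere genes had 32.4 and 7020 bp, and endothelial genes 18.6 and 4734.5 bp. Skeletal muscle genes were low in both (9.25 and 957 bp). Whether signal goes with breadth gene by gene was not tested. The design names no other group, so no explanation beyond CpG ratio and merging was tested.

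The marked promoters of transcription factors of other lineages, 24 of 24, were weighed against CpG-rich promoters and against cells of other organs. Random lists matched on CpG ratio had a median share of 95.8% and 100% at the upper limit of their central 95%, which is the highest share there is, so the test was saturated and CpG-rich promoters stay open. Cells of other organs in the pools stay open too. The 74 genes tested were those of hepatocytes, skeletal muscle, neurons with neural crest and Schwann cells, and lung and other epithelium. Of these, 39 were marked, and this 52.7% lay within the central 95% of matched lists (48.6% to 63.5%, median 55.4%). The 74 genes were not screened for genes that heart cells also use, so their share does not measure cells of other organs alone. No explanation beyond CpG-rich promoters and cells of other organs was tested, since the design names no other group.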
